A study of Panonychus citri with 4 samples.

How the data were processed

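Small RNAs were measured in whole citrus red mites (Panonychus citri) at 4 stages, embryo, larva, nymph and adult, with 1 library per stage. Per the labels' protocols, each library came from pooled animals, numbering over 3000 for the embryo library, 2500 for the larva, 1500 for the nymph and 1000 for the adult, the nymph pool held 2 kinds of nymph, and RNAs of 18 to 30 nucleotides were cut from a 15% polyacrylamide gel, ligated to adapters, amplified and sequenced on a Solexa (Illumina) instrument. Stages were taken from the labels' developmental stage field.

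Per the file headers, the authors deposited for each library a list of known miRNA names with a read count, a sequence and a normalized value. The read counts are whole numbers per name, as deposited by the authors. The normalized values deposited by the authors are reads per 1000000 (RPM): in every library the read count divided by the normalized value gave the same total in each row, between 5918115 and 5957910 reads, and these totals are called library totals here. Which reads the authors' library totals hold, the read-matching program, the miRNA reference, the mismatch rule and the genome build are not given in the sources used here. Every name had 1 sequence, and the 594 names over the 4 libraries had 594 sequences. A library lists only names with at least 1 read, and whether a read count covers reads of other lengths is not stated, so a name with no row is not evidence that the miRNA was absent.

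The listed reads came to 248256 in the embryo, 1012278 in the larva, 1258698 in the nymph and 438409 in the adult library. These are part of each library, so every comparison was also made with the library totals. At these depths 3 reads, taken as the floor for a name with no row, correspond to 12.1, 2.96, 2.38 and 6.84 reads per 1000000 listed.

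The choices named in this paragraph were fixed before the data were examined. Read counts were scaled to reads per 1000000 of the listed miRNA reads, and larva was compared with embryo, nymph with larva, adult with nymph and adult with embryo. The ratio of 2 libraries was given an exact conditional binomial (Clopper-Pearson) 95% interval, and a name with at least 30 reads over both libraries was said to differ beyond counting error when the interval lay wholly above 2-fold or wholly below its inverse. With 1 library per stage there is no replicate check, no test of the stages and no p-value across miRNAs, and all intervals cover counting error only, since amplified reads are not independent molecules. A stage peak needed a value at least 4-fold above each other stage, with every interval above 2-fold. The 14 miRNA lists were the let-7 complex, the miR-71/miR-2/miR-13 cluster, muscle, neuron and sense organ, Hox-cluster, growth and metabolism, the miR-34/miR-277/miR-317 cluster, the miR-92/25/310 family, the early embryo miR-309 cluster with its seed relatives, the miR-9/79/4 family, the miR-12 cluster, the miR-750/miR-1175 cluster, germline-linked, and other conserved miRNAs. A list of at least 3 measured names was placed among 10000 random lists of the same size, as a description of these libraries. The random lists were drawn from all tested names and matched on mean level, with names lacking a row set to their bound against 3 reads. Length variants of the same miRNA entered the lists by name as separate members. Names of plant type, looked for as a sign of ingested plant material, numbered 0.

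The names in the text follow a rule: in each comparison the 8 largest and 8 smallest ratios among names differing beyond counting error, the 10 names with the most reads in each library, all measured members of the let-7, miR-71/miR-2/miR-13, muscle, Hox-cluster and miR-92 lists, bantam and miR-184, up to 5 stage peaks per stage by reads, and precursors whose dominant arm changed. The rule gave 76 names. Where several rows belong to a family, the sum and its leading row are given, so that most length variants are described through their group, and vertebrate-type and most let-7 names as a class. Other names in the text were chosen after their values were seen.

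A second unit was added after seeing the data, because length variants of the same miRNA are listed under different names in different libraries. Names of the same family number were joined when their sequences overlapped without mismatch over at least 17 bases, with the most abundant name as leader, which gave 366 sequence groups. A group holds only the listed variants, and paralogs whose overlap agrees throughout cannot be told apart in it. Sequences with a mismatch in their overlap were kept apart, even where they share 17 or more bases in a row, so that variants of an abundant miRNA with a base difference stand as groups of their own. Vertebrate-type names, meaning 89 families known from vertebrates and not from arthropods, were also listed after seeing the data, and their sequences and those of let-7 are not printed.

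The alternatives were median-of-ratios scaling, the trimmed mean of M values (TMM, from edgeR), leaving the most abundant miRNA out of the totals, the library totals of the authors, other read minimums, 1.5-fold and 4-fold rules, thinning to the smallest library, and another pseudocount and filter for profile similarity. Added after seeing the data were sequence groups, names with a row in both libraries, and leaving out vertebrate-type and let-7 names. A call is said to hold under all 5 scalings when the interval passed the rule in the main scaling and in each of the 4 others. Profile similarity used log2 of reads per 1000000 plus a pseudocount of 1, over names with at least 30 reads in the 4 libraries.

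The comparison was tested on simulated data with known folds, drawn 100 times from the real means and depths. For larva against embryo (104 names, 34 changed) it recovered 75.0% of 4-fold and 98.9% of 8-fold changes. For nymph against larva (115 names, 38 changed) it recovered 87.1% and 100% of these, for adult against nymph (113 names, 37 changed) 83.7% and 99.7%, and for adult against embryo (99 names, 33 changed) 76.3% and 99.9%. At most 0.0146% of unchanged names were called, the changed names were called in the wrong direction in 0 cases, and 95.8% to 96.1% of intervals held the true ratio. The simulated reads were independent (Poisson) counts compared at the known listed totals, which is what the interval assumes. Amplification noise, the choice of scaling and variants listed under other names were not simulated, so these rates do not cover such errors.

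Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16 (TMM factors only) were used. Genome positions, precursors and gene annotation of the miRNAs were not analysed here.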

Results

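The 4 libraries describe the known miRNAs of the citrus red mite, a plant-feeding spider mite, from embryo to adult. Each stage was represented by 1 pooled library without replicates, so values compare these libraries and not the stages in general. Listed miRNA reads made up 4.17% of the library total in the embryo, 17.04% in the larva, 21.2% in the nymph and 7.41% in the adult, with 248256, 1012278, 1258698 and 438409 reads. The intervals given here are 95% Clopper-Pearson intervals and cover counting error only. Levels scaled to reads per 1000000 (RPM) of the listed miRNA reads are called listed RPM, and those scaled to the library total library RPM. Values named for a miRNA group are sums over length variants that overlap in sequence, with the group called by its leading name, and ratios are of listed RPM unless stated.

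The embryo library was led by miR-315 and miR-92-3p, which did not lead the other 3, while groups such as miR-1, miR-10-3p and miR-184 ranked high in every library. In the embryo, miR-315 (TTTTGATTGTTGCTCAGAAGGCG), which activates Wingless signalling when overexpressed in Drosophila, held 32.1% of listed reads (interval 32.0 to 32.3), and miR-92-3p (TATTGCACTCGTCCCGGCCT) held 19.9% (19.8 to 20.1). In the larva, nymph and adult libraries miR-1 (TGGAATGTAAAGAAGTATGGAG), a muscle miRNA, led as a group with 50.1% (50.05 to 50.2), 50.9% (50.8 to 51.0) and 47.1% (46.9 to 47.2), against 19.6% (19.5 to 19.8) in the embryo. Next in the larva and nymph came miR-184 (TGGACGGAGAACTGATAAGGGC), which acts in the Drosophila female germline, with 19.1% and 13.4%, and in the adult miR-34-5p (TGGCAGTGTGGTTAGCTGGTT), linked to ageing in Drosophila, with 17.5% (17.4 to 17.6). The name miR-5735-3p (TGGACAACAGGATAATGGCG) ranked 3 among groups in the larva, nymph and adult with 11.3% (11.2 to 11.3), 12.6% (12.5 to 12.6) and 10.7% (10.6 to 10.8), and 5 in the embryo with 4.09% (4.01 to 4.17).

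A small number of miRNAs held most reads at every stage. The 10 names with the most reads took 92.4% in the embryo, 92.1% in the larva, 89.0% in the nymph and 90.03% in the adult library. The embryo list held 262 names, the larva 273, the nymph 346 and the adult 270, of which 104, 118, 133 and 103 had at least 10 reads. Thinned to the embryo's depth, the larva, nymph and adult lists would hold 186.6, 214.3 and 226.7 names, so the nymph list was the longest at the nearly equal library totals but not at equal listed reads. All 4 libraries shared 105 names, or 140 sequence groups.

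The first comparison asked how the miRNA profile of the larva differed from that of the embryo. The groups miR-315, miR-92-3p and miR-92f-3p (TATTGCACTAGTCCCGGCCT) were 69.8-fold (67.8 to 72.0), 145.9-fold (138.3 to 154.0) and 33.8-fold (29.0 to 39.6) lower in the larva, and together these 3 took 52.7% of embryo reads and 0.615% of larva reads. The muscle miRNAs were higher in the larva, miR-1 by 2.55-fold (2.53 to 2.58) and miR-133 by 4.90-fold (3.30 to 7.57, from 26 embryo reads). The miR-34-5p group was 11.4-fold higher (10.6 to 12.2) and miR-317, which lies beside miR-34 in Drosophila, 5.27-fold higher (4.69 to 5.95). The miR-184 group was 5.896-fold higher (5.77 to 6.03), miR-87 was 13.8-fold (10.3 to 18.7), miR-276 6.67-fold (5.12 to 8.85), bantam, a growth promoter in Drosophila, 2.54-fold (2.14 to 3.03) and miR-5735-3p 2.76-fold higher (2.70 to 2.81). With the library totals every larva over embryo ratio was 4.09 times larger, so that miR-1 was 10.4-fold, miR-133 20.02-fold, miR-34-5p 46.6-fold, miR-184 24.1-fold and bantam 10.4-fold higher, and miR-315, miR-92-3p and miR-92f-3p 17.1-fold, 35.7-fold and 8.26-fold lower. The intervals do not cover this choice.

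Among sequence groups, 16 of 76 were higher in the larva and 34 lower, and all 16 higher but only 3 of the lower calls (miR-315, miR-92-3p and miR-92f-3p) held under all 5 scalings. The same count was 23 and 13 without miR-1 in the totals, 28 and 3 with TMM, 32 and 3 with median-of-ratios scaling and 34 and 3 with the library totals. By name, 30 of 104 were higher and 45 lower, of which 30 and 13 held under all scalings. The share of calls that were higher was 40.0% in listed RPM, 55.7% without miR-1 in the totals, 75.9% with TMM, 77.0% with median-of-ratios scaling and 80.3% with the library totals, which moved the median log2 ratio by 2.03. The groups miR-279-3p (3.73-fold lower, 3.62 to 3.84) and miR-993-5p (2.96-fold lower, 2.87 to 3.06) had ratios of 1.10 and 1.38 with the library totals, and miR-993-5p 1.03 with median-of-ratios scaling, none of them called.

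The lower calls of this comparison held names of 2 classes that mostly moved together. The let-7 complex list, taken from a complex linked to metamorphosis in Drosophila, had only let-7 names measured, most of them with letters. Whether these names belong to a mite counterpart of that complex was not tested. All 9 were lower in listed RPM (median log2 ratio -2.10), yet 0 of 9 differed beyond counting error with the library totals, where let-7, let-7e and let-7g stood at 1.10, 1.003 and 1.003. Likewise 17 of the 21 measured vertebrate-type names were lower in listed RPM, and 1 of the 17 held under all scalings. The other way, 2 of the 21 names were higher, both under all scalings, but as groups 16 of 18 were lower and 0 higher. Without these 2 classes, 28 names were higher and 19 lower. The plot of larva over embryo ratios shows the remaining groups on both scales.

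**Figure D1:**
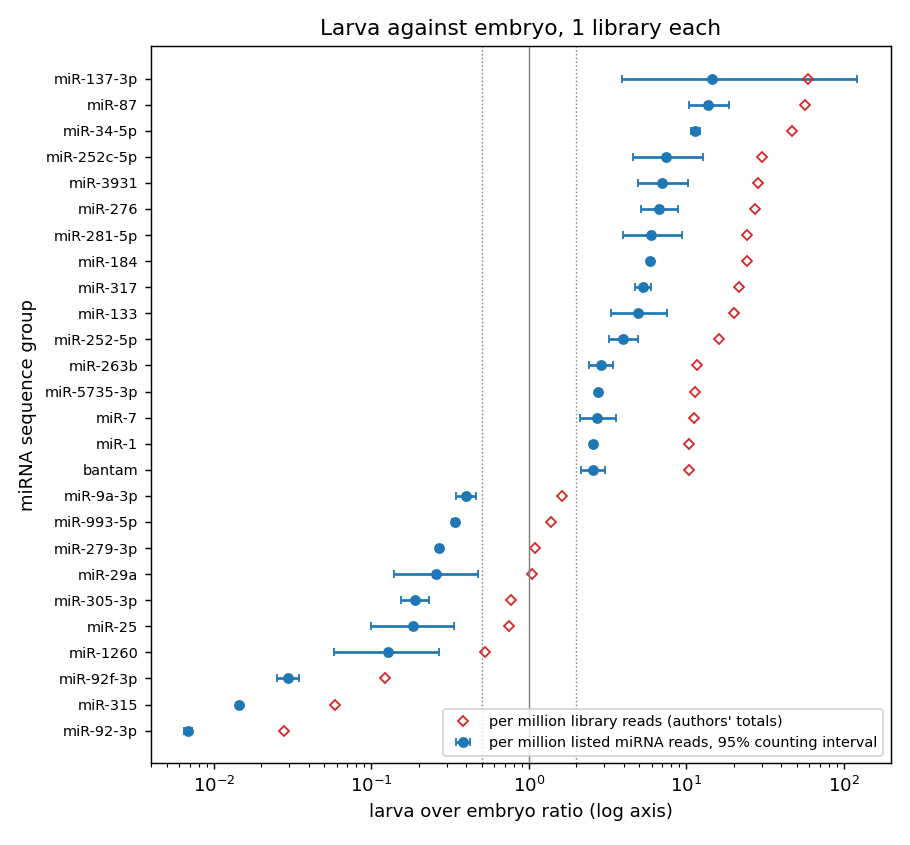
Ratios of larva over embryo (log axis) for miRNA sequence groups that differed beyond counting error, leaving out vertebrate-type and let-7 groups, with 1 library per stage. Blue points are ratios of listed RPM with 95% counting intervals, red diamonds the ratios of library RPM, and grey lines mark equality and 2-fold either way. Groups below equality on both scales include miR-315, miR-92-3p and miR-92f-3p, and nearer to equality by library RPM miR-25 and miR-305-3p. Those from miR-1 to miR-137-3p lie above on both scales, while miR-9a-3p, miR-993-5p, miR-279-3p and miR-29a change side.

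Other lists fixed beforehand were counted by name and, in a count added after the data were seen, by sequence group. In the muscle list 4 of 4 names and 2 of 2 groups were higher in the larva, and in the miR-34/miR-277/miR-317 list 3 of 4 names (percentile 97.1 of matched random lists) and 2 of 2 groups. The 4 names of the latter list were length variants of miR-34 and miR-317 alone, and their 2 groups were too few for a percentile. In the miR-92/25/310 list 4 of 4 names (percentile 1.67) and 3 of 3 groups were lower. Its member miR-25 (5.44-fold lower, 2.98 to 10.1) lost the call with the library totals, and its library RPM of 4.70, 3.53, 6.22 and 4.73 from embryo to adult varied 1.76-fold, within the range of the vertebrate-type groups. Among other conserved miRNAs 8 of 15 names were higher and 5 lower (percentile 99.99), against 5 and 2 of 10 groups (percentile 99.42). With the library totals this count was 10 and 3 of 15 names and 8 and 1 of 10 groups. The random lists also drew on the vertebrate-type and let-7 names, of which 17 and 9 were lower. This background can raise the percentiles of the other lists in this comparison. In neuron and sense organ 6 of 21 names were higher and 3 lower, against 3 and 1 of 12 groups, in growth and metabolism 3 and 2 of 8 names against 2 and 1 of 6 groups, and in germline-linked 3 and 1 of 7 names against 2 and 0 of 3 groups. The miR-71/miR-2/miR-13 cluster had 2 higher and 2 lower of 6 names but 0 calls among 3 groups, miR-9/79/4 had 1 and 1 of 3 names against 0 and 1 of 2 groups, and Hox-cluster 0 and 1 of 5 names and 0 and 1 of 4 groups. In the miR-12 cluster 0 of 2 names were called, the miR-309 list held only miR-279-3p, and the miR-750/miR-1175 list had 0 measured names. With the library totals 9 of 12 neuron, 4 of 6 growth, 3 of 3 germline-linked, 3 of 3 miR-71/miR-2/miR-13 and 3 of 4 Hox-cluster groups were higher and 0 lower, and by name 16 neuron, 6 growth, 6 germline-linked and 3 Hox-cluster names were higher.

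The size of the largest by-name ratios depended on which variant was listed, and the direction held for some of them when variants were joined. The 8 largest ratios all belonged to names with no row in the embryo, led by miR-252b-5p (at least 129.7-fold higher) and miR-263d-5p (at least 89.8-fold). Of these 8 names, 6 belonged to 5 groups that were higher under all 5 scalings at smaller folds, among them miR-87, miR-252c-5p (7.42-fold, 4.59 to 12.8), miR-281-5p (5.93-fold, 3.94 to 9.33), miR-252-5p (3.95-fold, 3.23 to 4.89) and miR-263b (2.86-fold, 2.40 to 3.42). The other 2 were not called higher as groups in listed RPM. The miR-190-5p group had a ratio of 2.42 (1.92 to 3.11) and was called higher under the other 4 scalings, from 3.91 without miR-1 in the totals to 9.91 with the library totals. The miR-9a-3p group had 0.399 (0.346 to 0.460), but 1.22 with median-of-ratios scaling, 1.04 with TMM and 1.63 with the library totals, where it had no call. Among the 8 smallest ratios 7 belonged to names with no row in the larva, led by miR-71 (at least 5105-fold lower), and 2 of the 8 belonged to groups called lower, miR-92-3p under all scalings and miR-9a-3p in listed RPM alone. The group of miR-2b, another of the 8, had a ratio of 1.13 (1.02 to 1.27), and was called higher with median-of-ratios scaling (3.47), TMM (2.95) and the library totals (4.63). For miR-71 the embryo listed 3756 reads of TGAAAGACATGGGTAGTGAGAT and 1161 reads of miR-71a-5p (TGAAAGACATGGGTAGTGAGA), where the larva listed 17904 reads of miR-71a-5p alone of this pair. The joined miR-71a-5p group had a larva over embryo ratio of 0.893 (0.865 to 0.922) in listed RPM alone. It stood at 1.44 without miR-1 in the totals and was called higher with TMM (2.32), median-of-ratios scaling (2.74) and the library totals (3.65). The leading rows of miR-34-5p (12.0-fold, 11.1 to 13.0), miR-184 (5.81-fold, 5.68 to 5.95), miR-1 (2.56-fold, 2.53 to 2.58) and bantam (2.47-fold, 2.06 to 2.99) lay close to their group values.

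The second comparison, nymph against larva, showed fewer differences. The groups miR-133 (5.09-fold, 4.64 to 5.60), miR-210-3p (4.24-fold, 3.72 to 4.83), miR-305c-5p (3.57-fold, 2.96 to 4.32), miR-12 (3.38-fold, 2.88 to 3.99) and miR-87 (3.03-fold, 2.90 to 3.16) were higher in the nymph under all scalings. Lower in the nymph were miR-263b, a miRNA of sensory bristles in Drosophila (2.98-fold, 2.73 to 3.27), miR-92-3p (2.79-fold, 2.54 to 3.08) and miR-315 (2.17-fold, 2.07 to 2.28), the last not past 2-fold under every scaling. The miR-263b fold rests on its variant miR-263d-5p, with 1098 larva reads and no nymph row. The row miR-263b itself stood at 527.5 listed RPM in the larva and 540.2 in the nymph. The miR-305c-5p fold likewise sets 616 nymph reads of 21 nucleotides against 139 larva reads of 22. The miR-1 group had a nymph over larva ratio of 1.01 (1.01 to 1.02), but 0.907 with median-of-ratios scaling, 0.883 with TMM and 1.26 with the library totals.

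Among sequence groups, 11 of 86 were higher and 3 lower, with 10 and 2 under all scalings. With the library totals 17 were higher and 2 lower, which raised the share of higher calls from 78.6% to 89.5%. By name, 26 of 115 were higher and 12 lower, and 22 of these calls concerned a name with no row in one of the libraries. The median log2 ratio was 0.31 higher with the library totals. All 16 names with the largest and smallest ratios lacked a row in one library, led by miR-124d-3p (at least 491.4-fold higher) and miR-124 (at least 3515-fold lower), whereas the joined miR-124-3p group, a neuronal miRNA, had a ratio of 1.86 (1.82 to 1.90) and was called higher with the library totals alone (2.31). Of the 8 largest and 8 smallest, 2 and 1 belonged to groups called in that direction, miR-305c-5p and miR-252b higher and miR-263b lower, while miR-7i-3p and miR-7-3p, named on opposite sides, joined to a ratio of 1.11 (0.842 to 1.47), with 0.992 and 0.966 under median-of-ratios scaling and TMM.

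By name, 3 of 6 members of the miR-34/miR-277/miR-317 list (percentile 96.1) and 8 of 17 other conserved miRNAs (3 lower, percentile 97.1) were higher in the nymph, against 1 of 3 groups (percentile 85.02) and 5 of 13 groups (1 lower, percentile 99.4). In neuron and sense organ 8 of 22 names were higher and 3 lower but only 1 and 1 of 14 groups, miR-210-3p and miR-263b. In growth and metabolism the count was 2 and 1 of 10 names against 1 and 0 of 7 groups, in Hox-cluster 1 and 1 of 7 names against 0 and 0 of 4 groups, and in germline-linked 1 and 0 of 7 names against 0 and 0 of 5 groups. The miR-12 cluster had 1 higher and 1 lower name, joined in the higher miR-12 group, muscle had 1 and 0 of 4 names and 1 and 0 of 2 groups, and miR-92/25/310 had 0 and 1 of 3 both by name and by group. The single miR-750/miR-1175 member, miR-1175b-3p, was higher, and 0 names or groups were called in the let-7, miR-71/miR-2/miR-13, miR-9/79/4 and miR-309 lists. With the library totals 3 of 7 growth, 2 of 3 miR-34/miR-277/miR-317, 1 of 4 Hox-cluster and 1 of 5 germline-linked groups were higher and 0 lower. In neuron and sense organ 2 of 14 groups were then higher and 1 lower, and among other conserved miRNAs 6 and 0 of 13 groups.

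The third comparison set the adult against the nymph. Lower in the adult under all 5 scalings were the groups miR-92-3p (7.65-fold, 5.24 to 11.6, 28 adult reads), miR-278-3p, which acts in energy balance in Drosophila (4.25-fold, 3.34 to 5.50), miR-263-5p (3.74-fold, 3.49 to 4.004), miR-92f-3p (3.09-fold, 2.25 to 4.33), miR-315 (2.64-fold, 2.36 to 2.96), miR-276 (2.29-fold, 2.08 to 2.53) and miR-87 (2.20-fold, 2.08 to 2.32), and miR-34-3p and miR-252b had no adult row against 32 and 43 nymph reads. The miR-278-3p fold rests mostly on different listed variants. The 826 nymph reads of miR-278-3p itself had no adult row, and 69 adult reads of miR-278b-3p had no nymph row. The variant miR-278, listed in both libraries, had 41 nymph and 2 adult reads. The library totals multiplied every adult over nymph ratio by 0.350. In listed RPM, miR-8-3p (TAATACTGTCAGGTAAAGATGTC), a regulator of insulin signalling and growth in Drosophila, was 5.81-fold higher (5.51 to 6.13), and its ratio with the library totals was 2.03. In the same way miR-252-5p (CTAAGTAGTAGTGCCGCAG) was 4.78-fold higher (4.59 to 4.98), and 1.67-fold with the library totals. The miR-34-5p group was 3.17-fold higher (3.14 to 3.21) but 1.11-fold with the library totals, and miR-317 was 2.60-fold higher (2.54 to 2.66) but turned to a ratio of 0.909 with them.

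Among sequence groups, 9 of 86 were higher and 9 lower, against 3 and 21 with TMM, 2 and 24 with median-of-ratios scaling and 0 and 39 with the library totals. Under all scalings 0 were higher and 9 lower. By name, 17 of 113 were higher and 24 lower, and 7 and 24 under all scalings. The share of calls that were higher was 41.5% in listed RPM, 22.9% with TMM, 19.6% with median-of-ratios scaling and 10.6% with the library totals (7 higher, 59 lower), which moved the median log2 ratio by -1.52. Among the 16 names with the largest and smallest ratios, only miR-8-3p and miR-92-3p had rows in both libraries, and the rest were led by miR-252-5p (at least 6018-fold higher) and miR-252b-5p (at least 438.5-fold lower), whose sequences overlap. As groups, 3 of the 8 largest were called higher, though 0 under all scalings, namely miR-8-3p, miR-252-5p and miR-716b (2.83-fold, 2.24 to 3.58, and 0.991 with the library totals), and 2 of the 8 smallest lower, miR-92-3p and miR-278-3p.

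In the list of other conserved miRNAs 4 of 18 names were higher and 7 lower in the adult (percentile 2.005), against 2 and 4 of 13 groups (percentile 1.745). With the library totals this count was 3 and 12 of 18 names and 0 and 8 of 13 groups. The random lists here also drew on 26 vertebrate-type and 9 let-7 names. The listed share of these 2 classes rose from 0.149% and 0.264% in the nymph to 0.318% and 0.505% in the adult. This background can lower the percentiles of the other lists in this comparison. In neuron and sense organ 2 of 19 names were higher and 7 lower (percentile 6.64), but 0 and 1 of 11 groups (percentile 12.18), the lower group being miR-263-5p. In miR-92/25/310 the count was 0 and 2 of 3 both by name (percentile 4.02) and by group (percentile 2.24), and in growth and metabolism 2 and 2 of 10 names against 1 and 2 of 7 groups. The miR-34/miR-277/miR-317 list had 3 higher and 1 lower of 6 names (percentile 93.3) and 2 and 1 of 3 groups, and with the library totals 0 were higher. Hox-cluster and germline-linked each had 0 higher and 1 lower of 6 names but 0 calls among 4 and 3 groups. No name or group was called in the let-7, miR-71/miR-2/miR-13, muscle, miR-9/79/4, miR-309, miR-12 and miR-750/miR-1175 lists. With the library totals 10 of 11 neuron, 6 of 7 growth, 4 of 4 Hox-cluster, 3 of 3 germline-linked, 3 of 3 miR-71/miR-2/miR-13, 2 of 2 muscle and 2 of 2 miR-9/79/4 groups were lower, as were the lone miR-309 and miR-12 groups, and by name 16 neuron, 8 growth, 6 germline-linked and 5 Hox-cluster names.

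The last comparison took the ends of the series, adult against embryo. The miR-34-5p group was 52.7-fold higher in the adult (49.2 to 56.5), miR-252-5p 36.1-fold (29.6 to 44.5), miR-317 25.5-fold (22.7 to 28.7), miR-281-5p 23.8-fold (15.9 to 37.3) and miR-8-3p 19.5-fold higher (16.3 to 23.6). The groups miR-133 (12.2-fold, 8.23 to 18.8), bantam (4.92-fold, 4.14 to 5.88), miR-184 (2.84-fold, 2.77 to 2.90) and miR-1 (2.40-fold, 2.37 to 2.42) were also higher. In the other direction, miR-92-3p was 3119-fold lower (2158 to 4695), with 49458 embryo and 28 adult reads, miR-315 400.3-fold (360.5 to 445.8), miR-92f-3p 63.0-fold (46.5 to 87.4) and miR-279-3p 5.73-fold lower (5.49 to 5.99). The Hox-cluster groups miR-10-3p (3.09-fold, 3.01 to 3.16) and miR-993-5p (3.15-fold, 3.03 to 3.28) were lower too, though not past 2-fold under every scaling. The library totals multiplied every adult over embryo ratio by 1.78, which gave 93.7-fold for miR-34-5p.

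Among sequence groups, 20 of 72 were higher and 7 lower, and 20 and 4 under all scalings. By name, 34 of 99 were higher and 17 lower, and 34 and 15 under all scalings. The library totals moved the median log2 ratio by 0.83. They gave 39 names higher and 15 lower. Among the 8 largest ratios were the rows miR-34-5p (51.3-fold, 47.52 to 55.45), miR-34 (58.6-fold, 50.1 to 69.0), miR-252-5p (36.0-fold, 29.5 to 44.3) and miR-317 (25.9-fold, 23.0 to 29.3), while the other 4 had no embryo row. Of the 8 smallest, 5 had no adult row, led by miR-71 (at least 2211-fold lower). As groups, 6 of the 8 largest were higher and 3 of the 8 smallest (miR-92-3p, miR-315 and miR-92f-3p) lower under all scalings.

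By name, 5 of 5 members of the miR-34/miR-277/miR-317 list (percentile 97.9) and 4 of 4 muscle names (percentile 74.7) were higher in the adult, as were 2 of 2 groups of each. The 5 names were length variants of miR-34 and miR-317 alone, and their 2 groups were too few for a percentile. In growth and metabolism 6 of 9 names were higher and 2 lower (percentile 96.1), against 3 and 0 of 6 groups (percentile 86.2), and among other conserved miRNAs 8 and 2 of 12 names (percentile 99.98) against 6 and 1 of 10 groups (percentile 99.6). In miR-92/25/310, 3 of 4 names were lower and 0 higher (percentile 1.09), against 2 and 0 of 3 groups, miR-25 not being called. The random lists of this comparison drew on 20 vertebrate-type and 9 let-7 names. The listed share of these classes fell from 0.548% and 0.922% in the embryo to 0.318% and 0.505% in the adult. Such a background can raise the percentiles of the other lists. In germline-linked 4 of 6 names were higher and 1 lower, against 2 and 0 of 2 groups, and in neuron and sense organ 5 and 3 of 17 names against 3 and 1 of 9 groups. The miR-71/miR-2/miR-13 cluster had 2 higher and 2 lower of 6 names but 0 calls among 3 groups. In miR-9/79/4 the count was 1 and 1 of 3 names against 0 and 1 of 2 groups, in the miR-12 cluster 1 and 1 of 2 names against 1 higher group, and in Hox-cluster 0 and 2 lower of both 5 names and 4 groups, with 0 lower by the library totals. The library totals also gave 0 lower groups in miR-9/79/4 and in neuron and sense organ. The lone miR-750/miR-1175 member was higher, the lone miR-309-list member miR-279-3p lower, and 0 of 9 let-7 names were called.

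**Figure D2:**
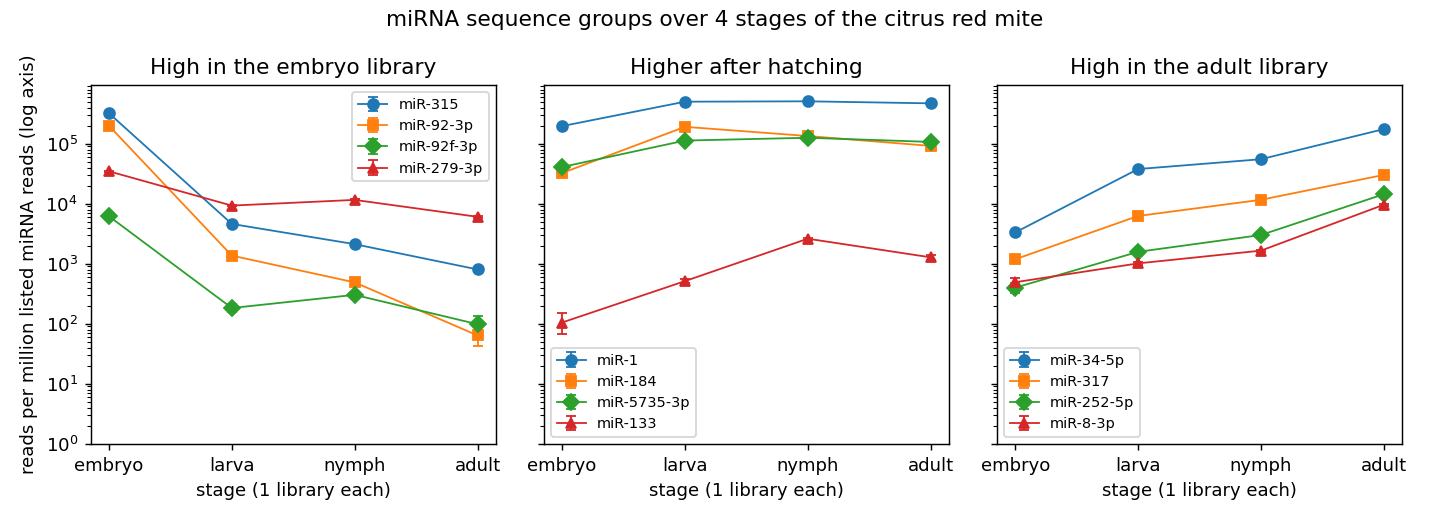
Listed RPM (reads per 1000000 listed miRNA reads, log axis) of 12 miRNA sequence groups in the embryo, larva, nymph and adult libraries, 1 library per stage, with 95% counting intervals and lines joining the stages for the eye. The left panel holds groups with their highest value in the embryo on this scaling, led by miR-315 at 32.1% of listed reads. With the library totals miR-279-3p was higher in the nymph (2451 library RPM) than in the embryo (1445). The middle panel holds groups higher in the later libraries than in the embryo. In the right panel are groups highest in the adult on this scaling, led by miR-34-5p at 17.5%. Its excess over the nymph was 1.11-fold with the library totals, and the ratio turned to 0.909 for miR-317.

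Stage peaks were few once length variants were joined. Among 102 groups, miR-92-3p (145.9-fold above the next stage), miR-315 (69.8-fold) and miR-92f-3p (20.4-fold) peaked in the embryo, and the rule was met in each of the 5 scalings, where the embryo had 3 peaks. With the library totals these folds came to 35.7, 17.1 and, at the edge of the 4-fold rule, 4.01. In the adult, miR-8-3p (5.81-fold), miR-252-5p (4.78-fold) and miR-6243a-5p (4.67-fold, 26 adult reads) met the rule. Whether the reads listed as miR-6243a-5p, or as miR-716b, come from a miRNA or from a fragment of a longer RNA was not tested, since no genome was used. With median-of-ratios, TMM and the library totals the adult had 0 peaks. The nymph had miR-252b (TTAAGTAGTAGTGCCGCAGGTA, 43 reads and no row elsewhere), which shares 20 bases in a row with miR-252b-5p (3777 nymph reads) of the miR-252-5p group and was left apart because the rest of their overlap has a mismatch. It met the rule only because a missing row was taken as 0 reads. Against the 3-read floor of 12.1 listed RPM in the embryo, its nymph level of 34.2 falls short of 4-fold. The nymph library had 4 peaks with the library totals, and the larva had 0. The counts by name also took a missing row as 0 reads. The nymph name miR-184d-3p (38.1 listed RPM), for instance, passed in this way, though short of 4-fold above the embryo floor of 12.1. By name, 29 of 139 met the rule (13 embryo, 4 larva, 6 nymph, 6 adult), of which 4, 0, 1 and 1 had a row in all libraries. The single such nymph name was miR-124-3p (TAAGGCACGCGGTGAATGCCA, 4.68-fold), and the adult name was miR-8-3p. The longer variant miR-124 had no nymph row, and the joined miR-124-3p group was 1.64-fold above the next stage, so it did not meet the rule.

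Both arms of 13 precursors were listed, and the dominant arm changed for miR-305 alone. The 5p arm of miR-305, which acts in Drosophila gut stem cells, held 21.8% (17.2 to 27.02) of the reads of both arms in the embryo, 44.1% (38.6 to 49.8) in the larva, 58.6% (55.6 to 61.6) in the nymph and 54.8% (49.7 to 59.9) in the adult. Its listed 5p variant differed too, with 64 embryo reads of 23 nucleotides and 139 larva reads of 22. The nymph and adult listed 616 and 211 reads of 21 nucleotides, while the 3p arm kept the same row. The arm change therefore cannot be told apart from a change of the listed 5p variant. The 5p arm of miR-993 stayed dominant, with 93.6% (93.1 to 94.2) in the embryo against 76.9% (76.1 to 77.6), 78.96% (78.4 to 79.5) and 79.5% (78.3 to 80.6) in the later stages. The miR-10 arms stayed unequal, with a 5p share between 0.397% and 0.501%. In all 4 libraries 6 precursors favoured the 5p and 6 the 3p arm. Arm shares rest on reads of the same library and do not depend on scaling.

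The length of the listed reads followed the leading miRNAs. Sequences of 23 nucleotides, the length listed for miR-315, made up 33.1% of embryo reads and 1.91%, 2.49% and 4.53% of larva, nymph and adult reads. Sequences of 22 nucleotides, such as miR-1 and miR-184, made up 37.6%, 71.6%, 63.7% and 53.3%. A 5′ U began 92.5%, 93.2%, 93.8% and 95.1% of reads.

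Across miRNA names, Pearson correlations of log2 values were 0.75 for larva and nymph, 0.71 for larva and adult, 0.70 for nymph and adult, 0.59 for embryo and adult, 0.55 for embryo and larva and 0.43 for embryo and nymph, with Spearman values of 0.71, 0.67, 0.69, 0.60, 0.51 and 0.39. With variants joined the Pearson values were 0.96, 0.94, 0.94, 0.77, 0.83 and 0.77 in the same order. The miRNAs are not independent replicates, and no p-value is given.

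Vertebrate-type names were listed in every library. Together 234 such names held 1361, 1385, 1881 and 1395 reads in the embryo, larva, nymph and adult, or 228.4, 233.1, 316.4 and 235.7 library RPM. The let-7 names held 384.4, 359.5, 558.5 and 374.4 library RPM. All other names together held 41055, 169795, 210857 and 73469 library RPM, a range of 5.14-fold against 1.39-fold for the vertebrate-type and 1.55-fold for the let-7 names. Among groups with at least 100 reads, the highest over lowest library RPM was at most 2.20 in the 14 vertebrate-type groups, and 2 of 47 other groups, miR-25 (1.76) and miR-29a (1.53), lay within that range.

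**Figure D3:**
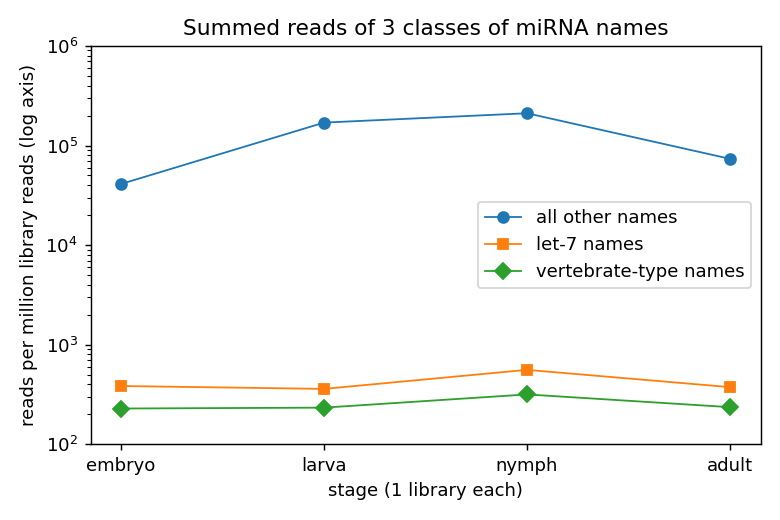
Summed library RPM (reads per 1000000 library reads, log axis) of let-7 names, vertebrate-type names and all other miRNA names in the 4 libraries, 1 library per stage. The vertebrate-type sum lies between 228.4 and 316.4 and the let-7 sum between 359.5 and 558.5 while the other names range from 41055 to 210857.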

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

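The counts with sequence groups, names with a row in both libraries and without vertebrate-type and let-7 names were chosen after the results were seen, and the other alternatives were planned. Of 222 checks of the main counts, medians and correlations, 156 stayed within 1.5 times or within their interval and 66 moved. Of 720 checks of single ratios of named miRNAs under the 4 other scalings, 189 stayed within the counting interval, 525 moved beyond it, and 6 called ratios crossed 1 and lost their call. Of the 720 ratios 632 stayed on the same side of 1 and 88 did not (36 of them with the library totals), and of the 276 checks of called ratios 216 kept the call and 60 lost it (21 with the library totals), counts that follow from the size of each scaling factor and the width of the intervals and do not rank the miRNAs. The embryo excess of miR-315 and miR-92-3p kept its direction under all 5 scalings. No paired analysis was possible because each stage had 1 library and the labels give no replicate numbers. Keeping rows of a name apart, chosen beforehand, gave nothing to run, since every name has 1 row per library. With median-of-ratios scaling, larva against embryo gave 47 names higher and 14 lower (groups 32 and 3), adult against nymph 9 and 37 (groups 2 and 24), and adult against embryo 4 groups lower. With TMM, larva against embryo gave 14 names lower (groups 28 higher, 3 lower) and adult against nymph 11 and 37 (groups 3 and 21). With the authors' library totals, larva against embryo gave 53 and 13 (groups 34 and 3), nymph against larva 17 groups higher, adult against nymph 7 and 59 (groups 0 and 39), and adult against embryo 4 groups lower. They also reversed the larva against embryo ratios of miR-279-3p (1.10), miR-993-5p (1.38), let-7 (1.10), let-7e (1.003) and let-7g (1.003), and the adult against nymph ratio of the single row miR-317 (0.935, and 0.909 for its group). A change of scaling multiplies every ratio of a comparison by the same factor, which by construction moves all these counts, but which scaling is nearer the amounts per animal was not tested. Without miR-1 in the totals, 13 groups were lower in larva against embryo and 4 in adult against embryo. The 4-fold rule gave 19 and 16 names for larva against embryo, 17 higher for nymph against larva, and 8 and 11 for adult against nymph, and the 1.5-fold rule 29 higher for adult against nymph and 26 lower for adult against embryo. With no read minimum, names lower came to 76 for larva against embryo, 23 for nymph against larva and 35 for adult against embryo, and names higher to 35 for adult against nymph. With at least 100 reads, names lower came to 24 for larva against embryo, 15 for adult against nymph and 10 for adult against embryo, and names higher to 17 for nymph against larva, since fewer names are tested. With a row in both libraries required, there were 18 names higher for larva against embryo, 14 and 2 for nymph against larva, 10 and 8 for adult against nymph, and 6 lower for adult against embryo. Without vertebrate-type and let-7 names, 19 names and 10 groups were lower in larva against embryo. Names joined by sequence left 7 stage peaks, with a missing row taken as 0 reads, and raised the Pearson correlations to 0.83 (embryo and larva), 0.77 (embryo and nymph), 0.77 (embryo and adult), 0.96 (larva and nymph), 0.94 (larva and adult) and 0.94 (nymph and adult). All listed names gave 0.704 for embryo and larva and 0.661 for embryo and nymph, and a pseudocount of 10 gave 0.852 for larva and nymph, causes not tested. A minimum of 10 reads left 104, 118, 133 and 103 names in the embryo, larva, nymph and adult, and thinning left 214.3 names in the nymph. Depth limits the names under 30 reads and any fold above an embryo value of few reads, such as miR-137-3p with 2 embryo reads.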

Other observations

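All 6 tests of explanations in this part were chosen after the results they bear on had been seen, and no stage difference could be tested with 1 library per stage. The miR-34-5p and miR-317 groups together took 0.450% of listed reads in the embryo, 4.40% in the larva, 6.67% in the nymph and 20.5% in the adult library, but their ratio to each other was not constant: miR-34-5p over miR-317 was 2.80 (2.45 to 3.21) in the embryo, 6.05 (5.89 to 6.22) in the larva, 4.75 (4.66 to 4.83) in the nymph and 5.80 (5.69 to 5.904) in the adult, a ratio that does not depend on scaling. The 5p arm of miR-7 also had a lower share in the embryo, 69.9% (59.5 to 78.97), than in the larva (88.7%, 86.3 to 90.8), nymph (91.6%, 90.05 to 92.9) and adult (89.6%, 86.5 to 92.2). The level of miR-92-3p in reads per 1000000 listed in the adult library was 0.0321% of its embryo level. The labels used here do not give the sex of the adults or whether they carried eggs.

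Vertebrate-type names and let-7 kept a nearly constant share of each library while the other names did not. Mite reads counted under vertebrate names in a fixed proportion to the other listed reads would keep the ratio of the 2 constant. The ratio of vertebrate-type to other reads varied 4.05-fold between libraries, so such a fixed proportion was not kept. This value restates the pattern that raised the explanation, and it does not cover mite reads that vary apart from the other listed reads. RNA of another organism, entering each library at a like share, and the same source for let-7 stay open: the vertebrate-type share of library reads varied 1.39-fold (highest over lowest) and the let-7 to vertebrate-type ratio 1.14-fold (1.54 to 1.77), but these values restate the pattern that raised the explanation and cannot decide it. The let-7 to vertebrate-type ratio differed between libraries beyond counting error (chi-square test on reads of these libraries, p = 0.0127), as did the mix of the 14 vertebrate-type groups (p = 0.000394, chi-square per degree of freedom 1.94, against 11848 for the other groups), while let-7a held 35.4% to 38.0% of let-7 reads (p = 0.242), and whether any let-7 comes from the mite stays open. These chi-square tests take reads as independent, which amplified reads are not, so they do not measure the spread between library preparations. The chi-square per degree of freedom also grows with the number of reads. The vertebrate-type groups held far fewer reads than the other groups, so 1.94 and 11848 do not compare how steady the 2 mixes were. When the RNA or reads entered and whether they came from the laboratory stay open, and no biological explanation was tested.

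The embryo library was dominated by miR-315 and miR-92-3p. Scaling alone would need the excess to vanish under some scaling, and the smallest embryo to later-stage ratio over 5 scalings and 3 libraries was 17.1. Carry-over of embryo reads as the sole source of these miRNAs in the adult library would leave both at a like share of their embryo level, and the adult share was 7.74 times (5.26 to 11.8) higher for miR-315 than for miR-92-3p. A difference between embryo and later stages is the biological explanation the design names, and a difference between library preparations, with 1 library per stage, remains open beside it.

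Names with at least 100 reads in some library and no row in another numbered 27, in 56 cases. A candidate explanation is that length variants of the same miRNA were listed under another name: in 100% of the cases the library without the name listed an overlapping sequence of the same family. The embryo and adult libraries, for instance, listed miR-190 as AGATATGTTTGATATTCTTG (77 and 600 reads), and the larva and nymph as miR-190-5p, AGATATGTTTGATATTCTTGGTT (761 and 1058 reads). Whether the most abundant variant itself differed between stages or the naming step chose differently could not be tested on lists with 1 sequence per name.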
